A study of Mus musculus with 6 samples.

How the data were processed

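Gene expression was measured in whole lungs of 6 mouse embryos at embryonic day 18.5, shortly before birth. Per the labels, the embryos came from an intercross of parents with 1 floxed allele of ECAT15-1 and 1 null allele of ECAT15-2, and each array held the RNA of 1 embryo. ECAT15-2 is the gene Dppa2 and ECAT15-1 is the gene Dppa4, which encode related nuclear proteins with a SAP domain that are known from pluripotent cells and early embryos. The 3 wild type embryos were 15-1+/+ and 15-2+/+. The 3 knockout embryos were 15-1Flox/Flox and 15-2-/-, so that the floxed ECAT15-1 allele went with the null ECAT15-2 allele in every knockout embryo. Per the labels' description, the line started from 129Sv embryonic stem cells, was mated to C57/BL6, and was crossed to a Cre or FLPe transgenic line of unknown background. The labels give neither the sex nor the litter of the embryos, and sex is read from sex-linked genes in the results.

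Per the labels' protocols, lungs were frozen, homogenized in Trizol and their total RNA was labelled with the dye Cy3. The design text names the Agilent Whole Mouse Genome array, which carries 4 arrays of 44K features per slide, hybridised with 1 colour. Per the file headers, slides were scanned and quantified with Agilent Feature Extraction 10.7.3.1, and the array design refers to the mouse assembly mm9. The deposited scanner files give an intensity per spot that this software had subtracted for background and detrended within the array, without any scaling between arrays. They also carry flags for spots that are saturated, not uniform, or well above background.

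The authors also deposited a table of log2 values for the same probes. The design text names GeneSpring GX 11 for the analysis and gives no scaling method. Set against the scanner files, each column of that table had a correlation of 1 and a slope of 1 with quantile-normalized log2 intensities, and the median of the 3 wild type arrays was 0 for 100% of the probes. The authors' log2 values were therefore normalized between arrays, with values equal to quantile normalization of log2 intensities within 0.001 (median absolute difference), and set relative to the wild type median. Their column medians were 0 for each wild type array and 0.0108, -0.00698 and -0.000844 for knockouts 1, 2 and 3.

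Each array held 43379 spots that are not controls, for 41174 probes. No spot was saturated. Between 77 and 110 spots per array had an outlier flag and were left out. Between 63.3% and 68.8% of the probes per array, or 26076 to 28336 probes, lay well above background. The 75th percentile of the intensities was between 1521.6 and 1687.9. The median standard deviation (SD) of log2 intensity between repeated spots of a probe within an array was between 0.0573 and 0.0739. The number of arrays, 3 per group, limits the precision of every comparison.

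The scanner files name probes by accession. Through a table of RefSeq genes on the assembly GRCm38.p6, 26690 of the 41174 probes (64.8%) received a current symbol, for 18217 genes, and the other probes kept the name in the file. That assembly differs from mm9, so the table was used for names and for the order of genes along a chromosome, and no coordinates are given.

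Log2 intensities were set relative to the array's 75th percentile, so that a level of 0 in the text is that percentile. Spots of a probe were averaged. Probes were kept if they lay well above background on all arrays of at least 1 group, which left 26669 probes. Each gene was represented by its probe with the highest mean over all 6 arrays, a choice that does not use the groups, which gave 19868 features (13940 with a symbol). Where another probe of a named gene had the opposite direction, differed by at least 1.5-fold from the value given or was below background on all 6 arrays, this is stated with the gene. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with no covariate, and a feature was called changed at a Benjamini-Hochberg adjusted p under 0.05. All changes are given as knockout minus wild type on the log2 scale. Where a probe was below background on every array of a group, the fold is given as a lower bound that was computed with the lowest intensity called well above background on each array.

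Gene lists for lung cell types, for other tissues that a lung dissection can hold, and for processes around birth were written before the data were examined, 35 in all. The 33 lists with at least 4 measured members were tested with limma's camera at its preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The lists of the targeted genes and of sex-linked genes had fewer members past the background filter and are given gene by gene. Fisher's exact test (two-sided) compared the share of changed genes on chromosome 16, and within 20 Mb of Dppa2, with the share elsewhere. The median size of change within 20 Mb was set against 10000 random sets of genes of the same number.

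Genes to name were also fixed in advance: a set list of 14 genes, the 10 largest rises and 10 largest falls among changed genes with a symbol whose groups did not overlap (clone names of the Rik and Gm kind passed over), the 4 members of smallest p in each list past the threshold, and 2 members in any other list described. A gene outside this rule is marked as chosen after its values were seen or stands under Other observations. The changed genes of chromosome 16 and the sex-linked genes are named as whole sets. A few genes that the rule takes are not reported here.

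The procedure was tested on simulated data for the comparison of knockout with wild type, with 19840 genes of which 200 were changed, in 20 draws. It called 4.1% of genes changed by 0.5 on the log2 scale, 73% at a change of 1, 94.6% at 1.5 and 98.5% at 2. On average 6.11% of the calls fell on unchanged genes (1.57% to 12.3% over the draws), and 4.87% of unchanged genes had an unadjusted p under 0.05. The first draw alone gave the highest of these shares, and after it was seen the number of draws was raised from 1 to 20. Camera was tried on 1 simulated data set without changes, and called 0 of 33 lists there. The simulated genes varied independently of each other and without batches, so this cannot show how camera treats lists whose genes vary together.

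The file headers give the slide of each array. Slide 1 held wild types 1 and 2 and knockout 3, slide 2 held wild type 3, and slide 3 held knockouts 1 and 2. The raw file names in the labels carry a further number whose meaning is not stated. Wild types 1 and 2 share one such number, wild type 3 and knockout 3 share another, and knockouts 1 and 2 share the last. Either grouping allows a comparison within 1 batch, with no replicate in at least 1 group. On slide 1 this is knockout 3 against wild types 1 and 2. Within the shared file name number it is knockout 3 against wild type 3. A fixed block for the slide or for the number estimates this same difference, so it rests on knockout 3 alone.

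Alternatives were a normexp background correction with an offset of 50, quantile and median scaling, other background filters, other rules for spots and probes, the authors' deposited values, other variance models, blocks for replicate number, slide and file name number, other thresholds and distances, and leaving out each array in turn. The normexp correction was to use mean spot intensities, which the deposited files do not give, and used the median spot intensities in their place. A normexp fit over all spots failed on knockout 3, where a few spots had very high local background: its 10th percentile came to 1440 on that array against 60.6 to 89.4 on the others, and 0 genes were called. After that failure was seen, spots with a feature or background outlier flag were left out of this fit. A term for wild types 1 and 2, and a comparison without these arrays, were added after the data were seen. Both set the knockouts against wild type 3 alone, so they estimate the same difference.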

Results

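The study asked how the lung of embryos that lack Dppa2 differs in gene expression from the wild type lung on the day before birth. RNA of 3 wild type and 3 knockout lungs was hybridised to 1 array each, and 66.1% to 66.6% of the probes on the wild type arrays and 63.3% to 68.8% on the knockout arrays lay well above background. Wild types 1 and 2 were closer to each other (SD of their log2 differences over genes 0.301) than any other pair of arrays (0.386 to 0.621). These arrays also had signal from the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and lacked signal from Xist, the RNA that coats the inactive X chromosome. Wild type 3 and the 3 knockouts had Xist and no Y-linked signal above background. Wild types 1 and 2 thus read as male and the others as female, so the groups were not balanced for sex. The limma difference for Xist, 7.92 on the log2 scale (4.46 to 6.31 at its other probes), did not pass the threshold (adjusted p = 0.145), because wild type 3 also had the transcript.

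Dppa2 itself had a level of -3.45 ± 0.17 on the log2 scale in wild type and -4.67 ± 0.51 in knockout lungs (SD, n = 3 each), a difference of -1.22 (standard error, SE, 0.25; 2.33-fold). This difference did not pass the threshold (limma adjusted p = 0.0604). The probe lay well above background on all 6 arrays, at -4.94, -4.98 and -4.08 in knockouts 1, 2 and 3. Knockout 3 differed by -0.69 from the mean of wild types 1 and 2 on the same slide and by -0.51 from wild type 3. Without knockout 3 the difference was -1.52 and passed (adjusted p = 0.0154). Whether the probe lies in the deleted part of the gene is not known here, so the signal neither supports nor contradicts the labels. The Dppa4 probe was below background on all 6 arrays.

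Scgb3a1, a secretoglobin of airway secretory cells, fell by 2.93 on the log2 scale in the knockout lungs (SE 0.30, 7.62-fold, n = 3 each). Gpnmb, a membrane glycoprotein of macrophages and pigment cells, was at least 4.69-fold lower, and Syce1, a protein of the synaptonemal complex of meiotic chromosomes, at least 2.31-fold lower, with all knockout arrays below background for either gene. Another Gpnmb probe was below background on all 6 arrays. Upb1, an enzyme of pyrimidine breakdown, fell by 2.64, and Reg3g, a secreted antimicrobial lectin, fell by 2.59. The odorant receptor gene Olfr920 fell by 2.56, and its probe was above background on 1 of the 3 knockout arrays. Myl3, a myosin light chain of heart and slow muscle, fell by 2.44, and had a difference of -1.37 at another probe. Aldh3a1, an aldehyde dehydrogenase, was at least 1.74-fold lower, and Pgam2, the muscle form of phosphoglycerate mutase, fell by 2.30.

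Pitx1, a homeobox factor known from the hindlimb and the pituitary, rose, with a fitted difference of 6.22. Its wild type signal was above background on 1 of 3 arrays and its knockout value rests on 2 arrays, because the spot of knockout 3 carried an outlier flag. Hba-x, the embryonic alpha-like globin, rose by 2.42 (SE 0.41, 5.36-fold, adjusted p = 0.0471). Abi3bp, an extracellular matrix protein, rose by 2.30, while another of its probes had a difference of -0.36 that did not pass. Timmdc1, a mitochondrial assembly factor of complex I, rose by 1.95 (3.85-fold). Dio3, the deiodinase that inactivates thyroid hormone, rose by 1.46, and Dio3os, the noncoding transcript opposite to it, by 1.26. Tagln3 rose by 1.43 (limma adjusted p = 0.0413), Cpne7, a calcium-dependent membrane-binding protein, by 1.38 (0.0323) and Fnd3c2 by 1.26 (0.0499). These calls were lost in 13 of 24, 11 of 24 and 17 of 23 alternatives, and that of Hba-x in 13 of 24. The Fnd3c2 probe was above background on 2 of 3 wild type arrays. Tmem145 was at least 2.17-fold higher, with wild type arrays below background.

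In total 267 of 19868 features changed (limma, adjusted p under 0.05), 144 of them higher and 123 lower in the knockout lungs, and 5101 had an unadjusted p under 0.05. The balance turned with the scaling, to 59 higher and 138 lower with quantile normalization, 60 and 137 with the authors' deposited values, and 88 and 230 with median scaling. Among the features with a symbol, 40 rose and 104 fell. Among the features without a symbol, 104 rose and 19 fell. At least 2-fold changes were found in 167 of the features, 69 higher and 98 lower. The groups did not overlap in any of the 267, and the same holds for 31.3% of all features tested. Chance gives 10% where arrays are exchangeable. These are not, since slides and file name numbers followed the groups in part, so the excess does not measure an effect of the genotype. The number of calls depended on single arrays: it was 36, 67 and 1926 without wild types 1, 2 and 3, and 95, 89 and 444 without knockouts 1, 2 and 3. With a term for wild types 1 and 2 it was 19 (1834 at an unadjusted p under 0.05), with the slide as a block 23, and with these 2 arrays left out it was 0 by limma (1459 at an unadjusted p under 0.05).

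The regulators and surfactant genes of the lung epithelium that were named in advance did not pass the threshold. Nkx2-1, the homeobox factor of lung identity, differed by -0.17 (95% confidence interval -0.49 to 0.16) and Foxa2, a forkhead factor of the airway and alveolar epithelium, by -0.29 (-0.57 to -0.02). The surfactant protein genes differed by -0.18 (Sftpa1; another probe, -0.51), -0.48 (Sftpb), 0.12 (Sftpc) and -0.50 (Sftpd). Stx3, a syntaxin of apical membranes, differed by -0.05, and by -0.37, -0.33 and -0.19 at its other probes. Gata4, a factor of heart development, was above background on 1 of the 6 arrays and was not tested.

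Cardiac muscle genes were lower in the knockout lungs. Of 26 tested genes of the list, 25 had a negative difference, 16 fell, 0 rose and 10 did not pass. Adjusted over the list alone, 23 fell and 1 rose, Corin, a protease that activates natriuretic peptides (0.92; chosen after its value was seen). Besides Myl3, the members of smallest p were Nkx2-5, the homeobox factor of the heart field (-1.73, SE 0.12, adjusted p = 0.00303), Csrp3, a Z-disc protein (-2.14), and Myl4, an atrial myosin light chain (-1.72). The mean over the list was -1.41 (SD over genes 0.76; -1.30 with the 2 genes below background in all knockouts set to their bounds). The list passed camera (adjusted p = 9.64e-22 over 33 lists), and had an adjusted p = 0.239 with an estimated correlation. The mean was -1.56 within slide 1, -1.48 between wild type 3 and knockout 3, and -1.36 with a term for wild types 1 and 2. Chosen after their values were seen, the abundant cardiac genes Myh7 (-0.29), Myh6 (-0.48) and Actc1 (-0.64) did not pass. Not all abundant members were like these. Myl7 (-1.46, chosen likewise) and Myl4 fell, with wild type levels of 3.74 and 1.87, against 1.57 for Myh6 and Actc1. Myh7 had the highest wild type level of the list, 5.25.

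**Figure D1:**
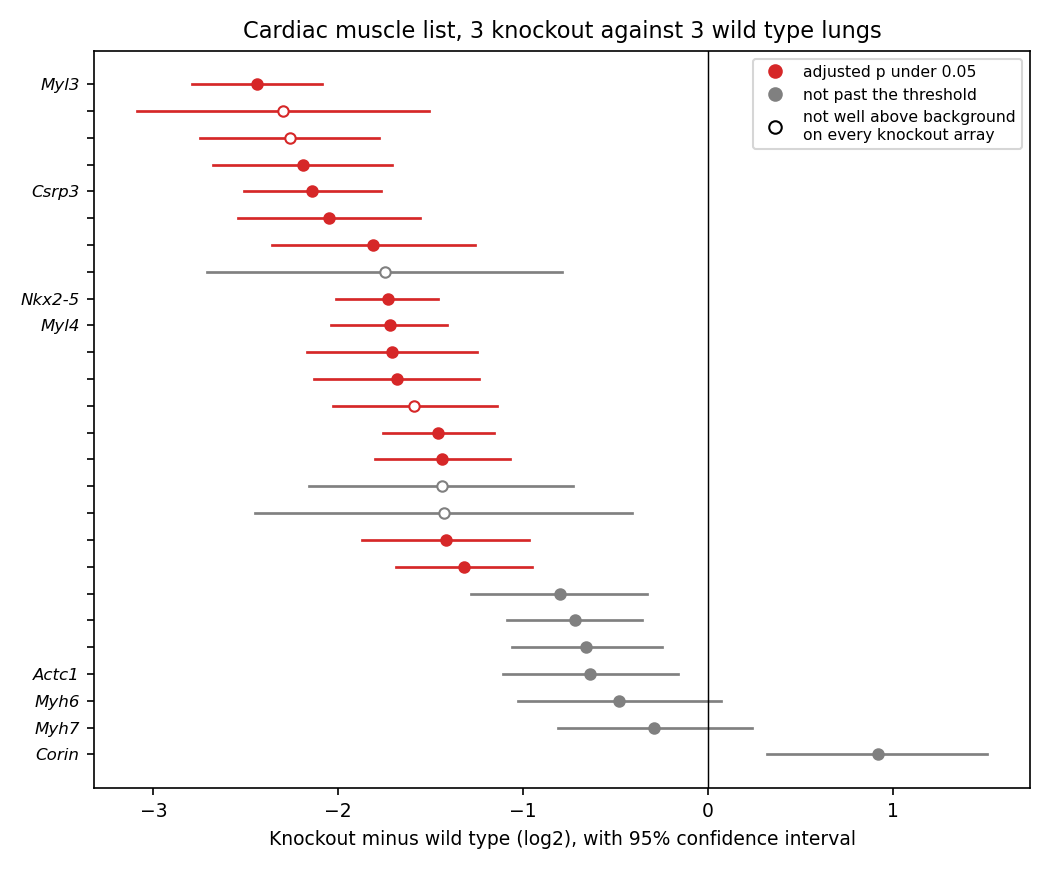
Difference between knockout and wild type lungs (log2, x axis) of each tested gene of the cardiac muscle list (y axis), 3 arrays per group. Bars give the 95% confidence interval, and labels mark some of the genes named in the text. Red marks the 16 genes at a limma adjusted p under 0.05, grey the other 10, and open symbols genes not well above background on every knockout array; 25 of 26 points lie below 0 and Corin lies above it.

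In the lists for skeletal muscle and for germ cells a few genes fell and most did not pass, with 5 of 13 and 3 of 10 members higher in the knockout lungs. In the list skeletal muscle 3 of 13 tested genes fell: Ckm, the muscle creatine kinase (-2.05, adjusted p = 0.00223), Pgam2, and Tnnt1, the slow skeletal troponin T (-1.25). Myl1, a fast and atrial myosin light chain, had a difference of -1.81 that did not pass, and another Myl1 probe was below background on all 6 arrays. Ckm and Pgam2 are also expressed in heart muscle. Adjusted over the list alone, 5 fell and 0 rose. The list's mean was -0.56 and its median -0.13, with a camera adjusted p = 0.0174 and an adjusted p = 0.371 with an estimated correlation. The mean was -0.61 within slide 1 and -0.59 between wild type 3 and knockout 3. The call was lost with median scaling (adjusted p = 0.0716; over the alternatives, from 0.00397 to 0.371).

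In the list germline and meiosis 2 of 10 tested genes fell, Tdrd1, a tudor protein of the piRNA pathway (-2.13, adjusted p = 0.00223), and Syce1. Another Tdrd1 probe was below background on all 6 arrays, and another Tex14 probe was above it on 1. Tex14, a protein of germ cell bridges, differed by -1.06 and Asz1, a further piRNA pathway gene, by 0.72, and neither passed. Adjusted over the list alone, 3 fell and 1 rose. The mean was -0.67 (-0.46 with Syce1 at its bound) and the median -0.29, with a camera adjusted p = 0.0174 and an adjusted p = 0.371 with an estimated correlation. It was -0.58 within slide 1 and -0.68 between wild type 3 and knockout 3, and the call was lost with median scaling (adjusted p = 0.0755), under the other background filters (means of -0.44, -0.25 and, with no filter, -0.06) and with the slide as a block (adjusted p = 0.0563). It was also lost without wild type 3 (-0.64, adjusted p = 0.0638) or knockout 3 (-0.55, adjusted p = 0.0659); over the alternatives the adjusted p ran from 0.00356 to 0.371.

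In the lists of neutrophil and mast cell markers and of airway secretory markers most differences were negative, and few genes passed singly. In the neutrophil and mast cell list 2 of 13 tested genes fell, S100a8, a calcium-binding protein of neutrophils (-0.98, adjusted p = 0.0375), and Mcpt4, a mast cell protease (at least 1.81-fold, adjusted p = 0.0499). Cma1, the mast cell chymase (-1.29), and Camp, the cathelicidin of neutrophil granules (-1.14), did not pass. Adjusted over the list alone, 10 fell and 0 rose. The mean was -0.90 (-0.81 with Mcpt4 at its bound; camera adjusted p = 3.64e-06, and adjusted p = 0.446 with an estimated correlation). It was -1.16 within slide 1, -0.60 between wild type 3 and knockout 3, and -0.52 with a term for wild types 1 and 2. In the club and secretory cell list 2 of 9 tested genes fell, among them Scgb3a1. Scgb1a1, the main secretoglobin of club cells, differed by -1.73 and did not pass (adjusted p = 0.0734), nor did Sec14l3, a lipid-binding protein of the airway (-0.35). Adjusted over the list alone, 4 fell and 0 rose. The mean was -0.88 (SD over genes 0.91; camera adjusted p = 0.000115, and adjusted p = 0.446 with an estimated correlation). The median was -0.42, since Scgb3a1 and Scgb1a1 differed more than the other members. The mean was -0.94 within slide 1, -0.58 between wild type 3 and knockout 3, and -0.64 with a term for wild types 1 and 2.

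A group of 5 lists passed camera with mean differences that shrank or changed sign with a term for wild types 1 and 2. These are the arrays with Y-linked signal. Some single members kept most of their difference with the term. In the proliferation list 0 of 25 genes passed singly, and all 25 had positive differences, among them the cell cycle genes Top2a (0.93), Kif20a (0.91), Mki67 (0.87) and Bub1 (0.78; another Bub1 probe, -0.06). The mean was 0.55 (camera adjusted p = 0.000224, and adjusted p = 0.611 with an estimated correlation). It was 0.70 within slide 1, -0.14 between wild type 3 and knockout 3, and -0.01 with a term for wild types 1 and 2. Without wild type 3 the mean of the list proliferation was 0.83. In the interferon response list 0 of 15 genes passed, and the members of small p included Rsad2 (-1.94; other probes, -1.32 and -1.22), Gbp2 (-0.40) and Isg15 (-1.42). The mean was -0.67 (camera adjusted p = 0.004, and adjusted p = 0.611 with an estimated correlation). It was -0.61 within slide 1 and 0.19 with the term. Between wild type 3 and knockout 3 it was 0.67, and with the file name number as a block the list passed camera in the opposite direction (adjusted p = 2.82e-06; over the alternatives, from 1.41e-06 to 0.612). Without wild type 1 the mean was -0.38 and the list interferon response did not pass, and without wild type 3 it was -1.09. In the alveolar type 2 and surfactant list 0 of 15 genes passed over all genes and 2 were lower adjusted over the list alone; Lyz2, a lysozyme (-1.09), and Scd1, a fatty acid desaturase (-1.42), had the smallest p, followed by Cebpa (-0.65) and Fasn (-0.40). The mean was -0.38 (camera adjusted p = 0.00515, and adjusted p = 0.611 with an estimated correlation). It was -0.39 within slide 1, 0.02 between wild type 3 and knockout 3, and -0.10 with the term. With the term Lyz2, Scd1, Cebpa and Fasn were at -0.58, -0.99, -0.19 and -0.25.

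In the macrophage and monocyte list 0 of 16 genes passed over all genes and 2 were lower adjusted over the list alone. The members of smallest p were Lyz1 (-1.12), Tyrobp (-0.46), Mpeg1 (-0.53) and Cd14 (-0.44). With the term these were at -0.76, -0.32, -0.11 and -0.09. The mean was -0.29 (camera adjusted p = 0.00639, and adjusted p = 0.611 with an estimated correlation), -0.23 within slide 1, 0.13 between wild type 3 and knockout 3, and -0.05 with the term. Without wild type 1 the mean of the list macrophage and monocyte was -0.20 and did not pass. In the mesothelial list 1 of 9 genes fell, Upk1b, a uroplakin (-1.47, adjusted p = 0.0375), which lies near Dppa2 on chromosome 16. It was also the 1 gene lower when adjusted over the list alone. Its difference was -1.36 between wild type 3 and knockout 3 and -1.33 with the term, so it did not follow wild types 1 and 2. Aldh1a2 (-0.64), Upk3b (-0.92) and Lrrn4 (-0.66) did not pass. The mean was -0.54 (camera adjusted p = 0.00754, and adjusted p = 0.611 with an estimated correlation), -0.75 within slide 1, -0.20 between wild type 3 and knockout 3, and -0.17 with the term. None of these 5 lists passed with the term (adjusted p between 0.404 and 0.722).

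Imprinted genes had a small positive mean difference. Of 25 tested genes 0 passed over all genes, 17 had positive differences, and adjusted over the list alone 2 rose and 0 fell. The members of smallest p were Magel2 (1.17), Peg3, a paternally expressed zinc finger gene (0.57), Mest (0.44) and Ndn (0.36), and none passed over all genes. The mean was 0.23 (camera adjusted p = 0.0174, and adjusted p = 0.371 with an estimated correlation), 0.30 within slide 1 and 0.20 between wild type 3 and knockout 3. With a term for wild types 1 and 2 it was 0.16 and did not pass (adjusted p = 0.0508), and without knockout 3 the list imprinted had a mean of 0.21 and did not pass (adjusted p = 0.11; over the alternatives, from 0.0035 to 0.371).

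**Figure D2:**
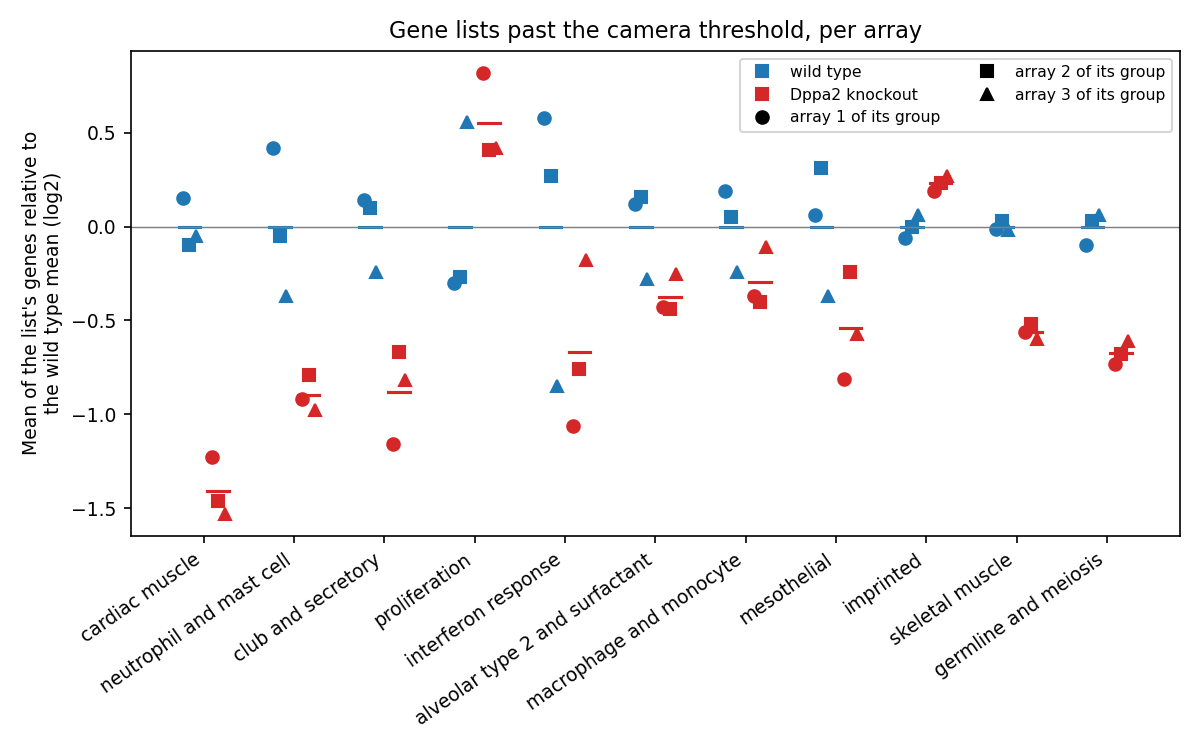
Mean of each list's genes relative to the wild type mean (log2, y axis) on each array, for the 11 lists past the camera threshold (x axis); points are arrays, shaped by replicate number and coloured by group, and bars are group means. Cardiac muscle genes lie between -1.53 and -1.23 on the 3 knockout arrays and between -0.10 and 0.15 on the wild type arrays, while in the proliferation list wild type 3 (0.56) lies among the knockouts (0.41 to 0.82).

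Of the 33 lists tested, 11 passed camera with the preset correlation, 2 with higher and 9 with lower means in the knockout lungs, and 0 passed with an estimated correlation. The other 22 had camera adjusted p-values from 0.0549 to 0.888. In the lung patterning list (mean 0.05) the members of smallest p were Foxp2 (0.49) and Shh (0.45), in the endothelial list (-0.02) Car4 (-0.79) and Pecam1 (0.57), and in the alveolar type 1 list (-0.03) Igfbp2 (1.15) and Aqp5 (-1.10), none of which passed. In the brown and white fat list (-0.39) Cox8b, a cytochrome oxidase subunit of brown fat and striated muscle, fell by 1.68 and Cidec differed by -1.17. In the neuroendocrine list (-0.15) Insm1, a zinc finger factor of neuroendocrine cells, was at least 1.26-fold lower. Syt1 differed by 1.00 at a probe that was above background on 2 of 3 wild type arrays. The other Syt1 probes were above background on 0 to 2 of the 6 arrays. In the erythroid list (0.29) Hba-x rose and Hbb-bh1, an embryonic beta-like globin, differed by 1.65 (adjusted p = 0.0786).

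Mean differences in the remaining cell type lists, none past the threshold, were -0.18 (ciliated), -0.57 (B cell), -0.27 (T cell and thymus), -0.20 (squamous epithelium), 0.29 (Schwann cell and glia), 0.14 (fibroblast and matrix), -0.26 (lymphatic endothelial), -0.04 (smooth muscle) and 0.09 (neuronal). In the lists of processes they were -0.19 (cholesterol synthesis), -0.16 (endoplasmic reticulum stress), -0.16 (p53 targets), -0.09 (immediate early), 0.43 (pluripotency and early embryo), -0.01 (glucocorticoid response) and 0.01 (hypoxia and glycolysis). Calls in some of these lists turned on the setting. The list ciliated gained a call with the slide or the file name number as a block, where the difference rests on knockout 3 alone. Its mean was -0.51 within slide 1 and -0.42 between wild type 3 and knockout 3. Its mean was -0.37 without knockout 2, where it passed, and -0.04 without knockout 3, and its adjusted p ran from 3.13e-06 to 0.771 over the alternatives. The list B cell passed with the slide as a block (-0.75, adjusted p = 0.00397; from 0.00397 to 0.611 over the alternatives) and without wild type 3 (-0.76) or knockout 2 (-0.67), and was -0.19 between wild type 3 and knockout 3. Calls were also gained without 1 array by the list T cell and thymus (-0.39 without wild type 2), the list cholesterol synthesis (-0.29 without wild type 3, -0.34 without knockout 1), the list brown and white fat (-0.47 without knockout 2) and the list immediate early (-0.42 without knockout 3). With the slide as a block the neuroendocrine (-0.36), fat (-0.55), cholesterol synthesis (-0.27) and immediate early (0.54) lists passed. With the file name number as a block the neuroendocrine (-0.23), fat (-0.39), immediate early (0.62) and lung patterning (0.21) lists passed.

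The sign of the mean differed from that of the median or of the camera test in the neuronal, erythroid, endothelial, glucocorticoid, hypoxia and lung patterning lists.

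Changed genes were more frequent near Dppa2, in a test fixed before the data were examined because linked 129Sv DNA can accompany a targeted allele. On chromosome 16, 13 of 441 tested genes with a symbol changed (2.95%), against 131 of 13499 on other chromosomes (0.97%). The odds ratio was 3.1 (Fisher's exact test, two-sided, p = 0.000652). Among the other chromosomes the share ran from 0.287% on chromosome 18 to 1.94% on chromosome 7. Within 20 Mb of Dppa2, 10 of 168 genes changed (5.95%), against 134 of 13772 elsewhere (0.973%; odds ratio 6.44, Fisher's exact test, p = 9.47e-06). Timmdc1, Tagln3, Abi3bp and the ephrin receptor gene Epha3 (1.23) rose there. Muc20 (-1.92), Stfa1 (-1.51), Arhgap31 (-0.91; another probe, -1.88), Upk1b, Cd200 (-1.20) and Cldnd1 (-0.77) fell. The other 3 changed genes of the chromosome, Rpl39l (-1.99), Cldn14 (-0.79), each above background on 1 of 3 knockout arrays, and Sh3bgr (2.01-fold lower), lay among the 273 tested genes of the chromosome outside this window. The median size of change within the window was 0.216 on the log2 scale, and 183 of 10000 random gene sets in a permutation test were as large (median 0.177, one-sided p = 0.0184). The odds ratio within 20 Mb did not pass Fisher's exact test with the slide as a block (5.88, p = 0.167) or with a term for wild types 1 and 2 (6.86, p = 0.146), where 23 and 19 features were called in all. It was 10.8 and 2.47 without wild types 1 and 3 and 4.04 without knockout 1, and that on the whole chromosome did not pass without wild type 2 (2.31), wild type 3 (1.34) or knockout 1 (2.54).

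**Figure D3:**
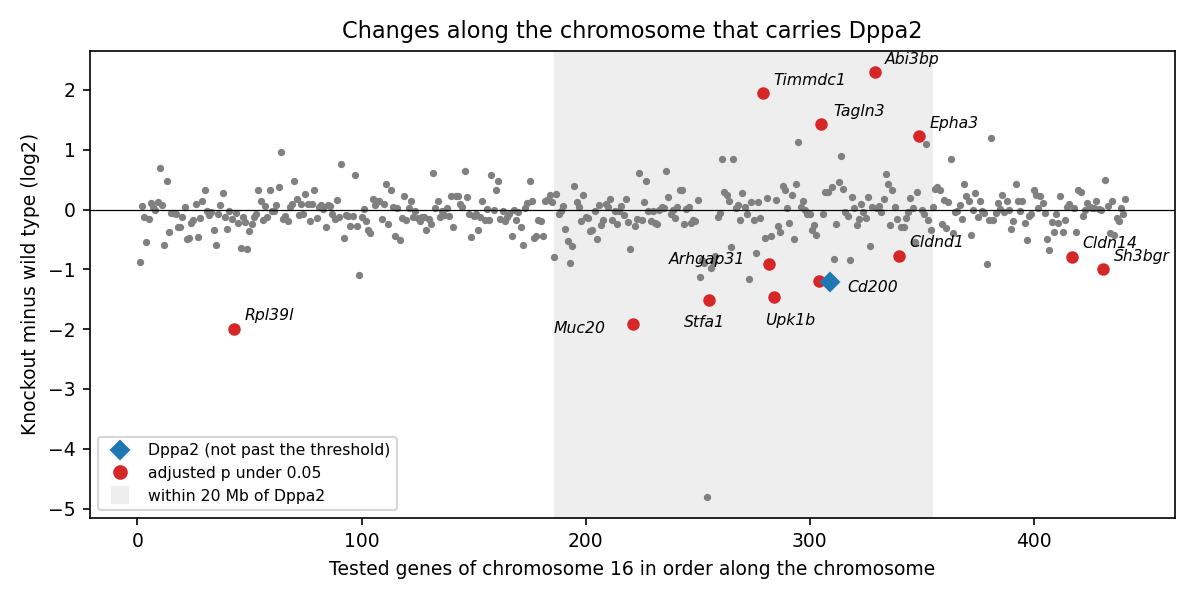
Difference between knockout and wild type lungs (log2, y axis) of the 441 tested genes of chromosome 16 in their order along the chromosome (x axis, rank). Red marks the 13 changed genes, the diamond Dppa2 (-1.22, not past the threshold), and the shaded region the 168 genes within 20 Mb of Dppa2, which hold 10 of the 13.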

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

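The counts of called genes moved by more than 1.5 times under many of the choices compared here. The term for wild types 1 and 2 and the comparison without these arrays were chosen after seeing the data, and the normexp fit was changed after its first form had failed. The mean of the cardiac list stayed negative under each alternative run (-1.56 to -0.98) and its call was lost in one, with an estimated correlation (-1.41, adjusted p = 0.239), where 0 lists passed. The replicate numbers did not pair the samples: deviations from the group means correlated at -0.02, 0.04 and 0.03 between arrays of the same number, and not every array correlated best with its own number. Signal over background limits the named genes whose arrays were below background, and for these a fold is given as a bound or the number of arrays is stated.

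Against 267 features called (144 raised, 123 lowered), normexp correction called 326, of which 165 were the same features. Quantile normalization called 197 (59 raised, 166 of them shared), the authors' deposited values 197 (60 raised, 167 shared), and median scaling 318 (88 raised, 230 lowered), where the median of all features moved to -0.12. The raised share of the calls was 53.9% in the reported comparison and 29.9%, 30.5% and 27.7% under these 3. With no background filter 28 were called (14 raised, 14 lowered), 17 lists passed, the median of all features was 0.14, and the odds ratio for chromosome 16 was 3.82 (Fisher's exact test, p = 0.11). With probes kept at 1 array above background 96 were called (42 raised, 54 lowered). A trended, robust variance gave 199 lowered features, and array weights gave 2212 (1442 raised, 770 lowered), with Dppa2 at -1.15 (adjusted p = 0.0345). An adjusted p under 0.1 gave 2047 (1325 raised, 722 lowered), a further 2-fold limit 167 (69 raised), and an unadjusted p under 0.05 with 2-fold 600 (316 raised, 284 lowered). The cause of these differences was not tested.

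With the replicate number as a block 54 features were called (16 raised, 38 lowered), 50 of them shared, and the ciliated list passed (adjusted p = 0.0214). With the slide as a block 23 were called (10 raised, 13 lowered), 8 of them shared, and the odds ratios were 2.19 on chromosome 16 and 5.88 within 20 Mb of Dppa2 (Fisher's exact test, p = 0.382 and 0.167), while the immediate early list turned to 0.54 and passed (adjusted p = 0.0194). With the file name number as a fixed block limma called 0 features (0 raised, 0 lowered; 1065 at an unadjusted p under 0.05), so no odds ratio could be had. In that fit, which rests on wild type 3 against knockout 3, the means turned to 0.02 (alveolar type 2), 0.13 (macrophage), -0.14 (proliferation), 0.62 (immediate early) and 0.67 (interferon response), and the last 2 passed camera in that direction (adjusted p = 8.43e-08 and 2.82e-06). As a random block (estimated correlation -0.201) it gave 1698 features (1090 raised, 608 lowered), with Dppa2 at -1.31 (adjusted p = 0.0331). With a term for wild types 1 and 2 limma called 19 (4 raised, 15 lowered; 1834 at an unadjusted p under 0.05), 10 of them shared, 5 lists passed, and the odds ratios were 2.56 and 6.86 (Fisher's exact test, p = 0.341 and 0.146). Without these arrays limma called 0 (0 raised, 0 lowered; 1459 at an unadjusted p under 0.05), with no odds ratio, and 6 lists passed. There wild type 3 was assumed to vary like the knockouts. In both, which set the knockouts against wild type 3 alone and so estimate the same difference, proliferation turned to -0.01 and interferon response to 0.19. The fixed blocks and the term leave fewer degrees of freedom, and the cause of these differences was not tested.

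Leaving out 1 array at a time gave 36 to 1926 features called, 11 to 1283 raised and 25 to 643 lowered, and 9 to 14 lists. The odds ratio lay between 1.34 and 5.55 for chromosome 16 and between 2.47 and 10.8 within 20 Mb. The cardiac mean lay between -1.49 and -1.33, and Dppa2 between -1.52 and -1.06 with a call without knockout 3. Of the values of named genes without 1 array, 556 kept their side of the threshold, 65 lost and 45 gained a call, and 0 turned. Under the blocks these counts were 339, 71, 31 and 0. A turn of direction was counted only where a call was involved. Values that turned without a call on either side count as kept. Of the other lists' values without 1 array, 179 kept their side of the threshold, 5 lost and 8 gained a call.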

Other observations

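Several single genes outside the lists fell in the knockout lungs. They were picked because they had fallen, so they show nothing of muscle genes as a group. They include the Z-disc genes Ldb3 (at least 2.21-fold), Actn2 (-1.19), Tcap (-1.21) and Myoz2 (-1.89), as well as Mybphl (-2.21), Cox6a2 (-1.77) and Mb, the myoglobin gene (-1.58; above background on 1 of 3 knockout arrays). Muc5b, an airway mucin, fell by 2.07. The embryonic globin genes Hbb-bh1 (1.65) and Hbb-y (1.85) had differences of the sign of Hba-x that did not pass. Csta2, a stefin gene within 20 Mb of Dppa2, differed by -4.80 with an SD of 2.59 over the knockout arrays and did not pass (adjusted p = 0.0743).

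Probes that carry a cDNA clone accession in place of a gene symbol were higher in the knockout lungs. Of 3074 such features 72 rose and 8 fell, with a median difference of 0.33, against -0.04 for genes with a symbol and 0.00 for those matched on level. Medians relative to the wild type mean were 0.40, 0.33 and 0.24 in knockouts 1, 2 and 3. The median was 0.18 with normexp correction, 0.21 with quantile normalization, 0.20 with median scaling and 0.15 with the file name number as a block. The counts depended on the setting: 62 rose and 9 fell with normexp correction, 25 and 10 with quantile normalization, 26 and 10 with the authors' deposited values and 42 and 20 with median scaling. With the slide as a block 2 rose and 3 fell, with a term for wild types 1 and 2 they were 1 and 2, and with the file name number as a block limma called 0 and 0 (1065 of all features at an unadjusted p under 0.05). No explanation of this difference was tested.

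The tests below were chosen after the result was seen, except for the counts over splits of the arrays. The Fisher test of genes near Dppa2 was itself fixed before the data were examined, and was weighed as a test of linked strain DNA after its result was seen. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many changed features as the 267 of the real one, which was the real split itself, and the highest other gave 1. As many lists as the 11 of the real split were found in 4 splits, the real one included, with 12 in the highest other; the split of slide 1 from the rest gave 11, and the list means within slide 1 are given with each list. With 10 splits the share can never be under 0.1. Each other split mixes the genotypes unevenly on either side, so part of the group difference remains in it. The counts of these splits therefore do not show what would be found without a group difference. In them the cardiac list had camera adjusted p-values from 5.01e-09 to 0.126, with means from -0.65 to 0.49.

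Cardiac muscle genes were lower on each knockout array. The mean of -1.36 with a term for wild types 1 and 2, and of -1.56 with the slide as a block, argues against either as the whole source. More heart tissue left on the wild type lungs could give such a difference, and Myh7, an abundant heart transcript, differed by -0.29, but its high level in the knockout lungs (4.96) could hide a small share of heart RNA, so this stays open. Fewer cardiac muscle cells in the pulmonary veins of the knockout lungs, where Myl7, Myl4 and Nkx2-5 are known to be expressed, may also be a source, and was not tested. These genes fell, while the cardiac genes Myh6 (-0.48), Actc1 (-0.64) and Myh7 did not pass, so single members do not decide this either.

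The proliferation, interferon response and alveolar type 2 differences are consistent with wild types 1 and 2 standing apart from the other 4 arrays. With a term for these arrays the means were -0.01, 0.19 and -0.10, and with the file name number as a block the interferon response list passed with a higher mean in the knockout (0.67). The 2 arrays share their slide with knockout 3 alone, share a file name number with no other array, and have Y-linked signal, so that sex, litter or stage and the work behind the number cannot be told apart. An effect of the genotype on these lists stays open and rests on wild type 3 against the knockouts.

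Changed genes near Dppa2 were more frequent than elsewhere (odds ratio 6.44), in both directions, which is consistent with 129Sv DNA that accompanied the targeted allele through the crosses to C57/BL6. A variant under the probe, in place of a difference in expression, may account for some of them. Of 5 changed genes with another probe, 4 (Tagln3, Cldnd1, Arhgap31 and Epha3) had the same direction there at an unadjusted p under 0.05 by limma, and Abi3bp had not, while the remaining changed genes near Dppa2 had no other probe to compare, so a variant stays open. An effect of the lost Dppa2 protein on neighbouring genes was not tested and stays open.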
